A study of Mus musculus with 10 samples.

How the data were processed

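RNA sequencing of 10 libraries of a mouse Ph+ acute lymphoblastic leukaemia line was analysed from the table of counts per gene that the authors deposited. Per the submitters' processing notes, the reads were handled with CASAVA 1.7.0, Trimmomatic 0.33, TopHat2 2.0.12, BWA 0.7.10 and SAMtools, and the counts were made with HTSeq 0.6.1 against mm9. The strand setting of the counting was not given in the sources used here, so overlapping or antisense genes cannot be told apart, nor can close paralogs. The deposited per-sample values that are not counts were not used here. The reads were not analysed here. The dasatinib libraries carry the words biological replicate in their titles and the parental ones the word replicate, and nothing shows that they came from separate cultures, so the p-values measure only the spread between these samples.

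Of 29955 genes, 18621 had a count, and 12282 passed filterByExpr of edgeR at its minimum count of 10 and were tested. They held 99.96 to 99.98% of the counts of each library. The report gives the total counts of each library. CPM were computed by edgeR on the TMM-effective library sizes. The median log2 change of all genes was -0.01 to 0.013 over the comparisons. Log2 CPM for lists used a prior count of 2.

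Tests were made in R 4.3.3 with the robust quasi-likelihood test of edgeR 4.0.16 and adjusted by Benjamini and Hochberg at 0.05. The 3 main comparisons used a fit of 3 classes, in which the parental and both DMSO lines formed the drug-free class. Its biological coefficient of variation was 15.3% on 7 residual degrees of freedom. The 4 comparisons with a single DMSO library used a fit of 5 groups, at 7.27% on 5 degrees of freedom. Of 29 lists written from general knowledge, the 28 with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation. Some genes are members of several lists. The comparisons, tests, lists, naming rule and first set of other settings were fixed before the data were examined.

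The naming rule took, per main comparison, the 8 called genes with the highest and the 8 with the lowest log2 change, and 3 each for the single-control comparisons. These had to reach a mean of 5 CPM in one group and to have no overlap between the groups, and predicted genes were left out. For the main comparisons it added the 2 members of each list with the smallest called p-values, without those conditions, and Abl1, the drug's target, whether called or not. The report describes only part of the genes the rule names, chosen after their values were seen, and names further called list members without their levels. Where a group had 0 counts, a lower bound on the fold was computed with a floor of 3 counts over the group. With 1 to 3 counts, a ratio with a 95% counting interval is given. Bounds and intervals cover counting error only.

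The procedure was tested on simulated data with 200 changed genes. In the order all, 1.5-fold, 2-fold and 4-fold, the percent recovered was 70, 58.2, 62.7 and 89.4 for dasatinib 1x against drug-free (12155 genes tested, 8 false calls), 70, 49.3, 74.6 and 86.4 for 16x against drug-free (12151 and 4), and 77, 59.7, 83.6 and 87.9 for 16x against 1x (12153 and 9). It was 67, 56.7, 64.2 and 80.3 for 1x against DMSO 1x (12158 and 3), and 73, 59.7, 77.6 and 81.8 for 16x against DMSO 16x (12153 and 7). It was 61.5, 38.8, 65.7 and 80.3 for DMSO 1x against parental (12141 and 10), and 71, 58.2, 68.7 and 86.4 for DMSO 16x against parental (12153 and 7). DESeq2 made 39, 38 and 45 false calls in the 3 main comparisons. The lists were tested on simulated data for dasatinib 16x against drug-free alone. No list was called without a change in 10 tables. An S phase list shifted by 0.3 on the log2 scale was recovered in 10 of 10. Genes were drawn independently, so false calls of lists whose members vary together were not tested. In the data the estimated correlation was 0.409 for oxidative phosphorylation and 0.755 for histones, but 0.037 for S phase genes. The S phase median change in that comparison, -0.11, was smaller than the shift.

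The other settings fixed at that point were RLE scaling, no filter, DESeq2 1.42.0, limma-voom, a block by replicate letter, only the libraries of the 2 classes, a threshold of 2-fold, parental or DMSO libraries alone as reference, camera with an estimated correlation, fry, and leaving out each library. Added after seeing the data were a fit of 5 groups with the mean of the drug-free groups, the same alternatives for the overlap, and all tests without the genes of chromosomes 5 and 18. For the overlap, all 10 libraries, the shared controls included, were simulated without change from the drug-free mean in 20 draws. Chromosome, gene order, length and GC content came from a GRCm38.p6 RefSeq table and GENCODE vM21, which matched 11324 tested genes by name, while the counts were made against mm9. No coordinates are given.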

Results

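RNA sequencing was done on 10 libraries of a mouse acute lymphoblastic leukaemia line that carries BCR-ABL1, the fusion kinase of the Philadelphia chromosome, in its p185 form. Of these, 2 came from the parental line, 3 from lines that had grown out under dasatinib at dose step 1x of the IC90, and 3 from lines that had grown out at 16x. A single library each came from lines carried with the solvent DMSO to 1x and to 16x. Dasatinib inhibits the ABL and SRC family kinases. Total counts were 29049760 and 41349084 for parental A and B, 36439125 for DMSO 1x and 37160252 for DMSO 16x. They were 31695307, 40185039 and 39832388 for dasatinib 1x A, B and C, and 45813092, 40648908 and 42330324 for dasatinib 16x A, B and C. Counts were found for 18621 of 29955 listed genes, and 12282 genes were tested.

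On the first principal component (48.3% of the variance) the parental libraries stood at -22.9 and -22.4, with all 6 dasatinib libraries on one side (19.8 to 34.1) and both DMSO lines on the other (-45.9 and -68.7). The second (24.3%) set both 16x steps apart: DMSO 16x stood at 38.4 and the dasatinib 16x libraries at 22.2 to 28.2, against -20.5 to -15.6 for dasatinib 1x. The most abundant gene, Eef1a1, took 0.94 to 1.07% of the counts.

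**Figure D1:**
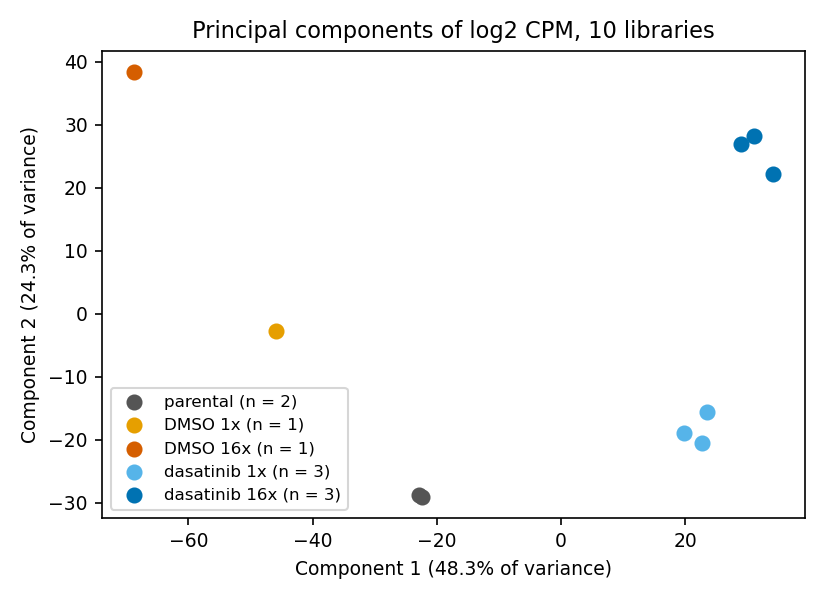
Scores of the 10 libraries on the first 2 principal components of log2 CPM, each point 1 library coloured by group. The dasatinib libraries lie at 19.8 to 34.1 on the first component, the parental libraries at -22.9 and -22.4, and the DMSO lines at -45.9 and -68.7.

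The first comparison set the dasatinib 1x lines (n = 3) against the 4 drug-free libraries (parental and DMSO), to ask which genes differed once the line had grown out at the first dose step. Values are mean CPM ± SD, and log2 changes are given ± SE. Spna1, the erythroid alpha chain of spectrin, rose to 8.63 ± 1.98 from 0.0521 ± 0.0503 CPM (log2 change 7.22 ± 0.6, adjusted p = 0.00253). Micall2 rose to 15.4 ± 4.19 from 1.87 ± 0.629 CPM (log2 change 3.03 ± 0.29, adjusted p = 0.00311). It lies on chromosome 5, whose genes stood lower in the DMSO lines. Slc22a8, an organic anion transporter, rose to 7.66 ± 0.483 from 2.37 ± 0.301 CPM (log2 change 1.69 ± 0.17, adjusted p = 0.00311), and Hmox1, haem oxygenase 1, to 7.72 ± 0.545 from 3.01 ± 0.332 CPM (log2 change 1.36 ± 0.12, adjusted p = 0.00253). These 4 genes passed whichever of the 10 libraries was left out, with adjusted p of at most 0.0307. Over all alternatives the adjusted p of Micall2 ranged over 5.82e-22 to 0.0586, so its call was lost under another setting. For the 4 genes, and for every other called gene given with its level in this comparison, all 3 dasatinib libraries lay beyond all 4 drug-free ones. The naming rule required this of the highest and lowest genes, though not of list members. Abl1, the gene of the drug's target, was not called (198 ± 2.39 against 194 ± 11.3 CPM, log2 change 0.03 ± 0.04, adjusted p = 0.691; range over all alternatives 0.0461 to 0.981, the lowest with the DMSO libraries alone as reference), and its own reads and those of the fusion cannot be told apart.

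Single genes of other groups passed the test as well. Bbc3, which encodes the pro-death protein PUMA, rose to 20.9 ± 0.475 from 13.8 ± 0.846 CPM (log2 change 0.6 ± 0.07, adjusted p = 0.00906). Itgal, the alpha chain of the integrin LFA-1, rose to 90.3 ± 1.6 from 46.7 ± 3.01 CPM (log2 change 0.95 ± 0.13, adjusted p = 0.0115). Tfrc, the transferrin receptor, fell to 810 ± 22.2 from 989 ± 35.7 CPM (log2 change -0.29 ± 0.04, adjusted p = 0.0126). Bcl11a, a transcription factor of early B cells, fell to 135 ± 3 from 162 ± 5.04 CPM (log2 change -0.27 ± 0.04, adjusted p = 0.0135), and Ddx58, the RNA sensor RIG-I, to 3.56 ± 0.749 from 8.62 ± 1.44 CPM (log2 change -1.28 ± 0.19, adjusted p = 0.0137). The lists that hold some of them were not called at 1x, namely pro-death BCL2 genes (1 rose and 0 fell of 9, list alone 1 and 1, median 0.11, adjusted p = 0.151), cell adhesion and migration (1 rose and 0 fell of 28, list alone 1 and 0, median -0.07, adjusted p = 0.962) and pro-B and pre-B cell identity (0 rose and 1 fell of 31, list alone 0 and 1, median -0.04, adjusted p = 0.297). The list with Ddx58 was not called either, interferon response (0 rose and 1 fell of 32, list alone 0 and 1, median -0.09, adjusted p = 0.297), nor that with Tfrc, erythroid and megakaryocytic cells (1 rose and 1 fell of 7, list alone 1 and 1, median -0.12, adjusted p = 0.863). The call of each of these 5 genes was lost without at least 1 of the dasatinib 1x libraries. Left out 1 at a time, the adjusted p of Bbc3 was 0.062 without dasatinib 1x A and 0.0618 without dasatinib 1x B (range over all alternatives 5.04e-09 to 0.062). For Itgal it was 0.0669 without dasatinib 1x A, 0.0715 without dasatinib 1x B and 0.0575 without dasatinib 1x C (range over all alternatives 4.66e-10 to 0.129). For Tfrc it was 0.0669 without dasatinib 1x A, 0.0919 without dasatinib 1x B and 0.0614 without dasatinib 1x C (range over all alternatives 7.01e-09 to 0.0919). For Bcl11a it was 0.091 without dasatinib 1x A, 0.0715 without dasatinib 1x B and 0.0631 without dasatinib 1x C (range over all alternatives 1.44e-07 to 0.091). For Ddx58 it was 0.0849 without dasatinib 1x A, 0.0587 without dasatinib 1x B and 0.0579 without dasatinib 1x C (range over all alternatives 6.25e-08 to 0.0849).

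Among the widest falls were genes with few or no reads at 1x. Fpgt had 0 counts in the 3 dasatinib libraries against 11.4 ± 11.6 CPM, at least 420-fold lower (adjusted p = 0.0367). Wbp5, also with 0 counts there, was at least 268-fold lower than 7.23 ± 7.73 CPM (adjusted p = 0.0486). The bound of Fpgt was 270 without dasatinib 1x B, 270 without dasatinib 1x C and 220 without DMSO 16x, and that of Wbp5 172 without dasatinib 1x B, 172 without dasatinib 1x C and 137 without DMSO 16x. Zfp182, a zinc finger gene, had 1 count in the 3 libraries, a ratio of 748 (95% counting interval 134 to 29600), with adjusted p = 0.0249. The ratio was 480 without dasatinib 1x B, at least 157 without dasatinib 1x C and 363 without DMSO 16x. All of these stood highest in DMSO 16x (Fpgt 27.6, Wbp5 17.8, Zfp182 16.8 CPM) and lower in the parental libraries (Fpgt 2.73 and 3.16, Wbp5 1.64 and 1.32, Zfp182 1.4 and 1.84 CPM). Blk, a SRC family kinase of B cells, fell to 5.2 ± 0.484 from 35.3 ± 15.1 CPM (log2 change -2.76 ± 0.54, adjusted p = 0.0418), and was also highest in DMSO 16x (57.1 CPM). The adjusted p of Fpgt was 0.0913 without DMSO 1x, 0.129 without dasatinib 1x A, 0.137 without dasatinib 1x B, 0.128 without dasatinib 1x C, 0.0553 without dasatinib 16x A, 0.0599 without dasatinib 16x B and 0.0575 without dasatinib 16x C (range over all alternatives 6.3e-09 to 0.206). That of Wbp5 was 0.107 without DMSO 1x, 0.159 without dasatinib 1x A, 0.164 without dasatinib 1x B, 0.164 without dasatinib 1x C, 0.0734 without dasatinib 16x A, 0.0769 without dasatinib 16x B and 0.111 without dasatinib 16x C (range over all alternatives 8.27e-08 to 0.207). For Zfp182 it was 0.0639 without DMSO 1x, 0.129 without dasatinib 1x A, 0.137 without dasatinib 1x B and 0.145 without dasatinib 1x C (range over all alternatives 2.42e-08 to 0.199). That of Blk was 0.0989 without DMSO 1x, 0.188 without dasatinib 1x A, 0.179 without dasatinib 1x B, 0.172 without dasatinib 1x C, 0.0792 without DMSO 16x, 0.0646 without dasatinib 16x C and 0.0549 without parental A (range over all alternatives 3.23e-05 to 0.265).

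Of the 28 fixed gene lists tested, 5 passed at 1x, and none of the 5 with an estimated correlation. The p53-induced genes rose as a list (median log2 change 0.2, adjusted p = 2.69e-05, and adjusted p = 0.15 with an estimated correlation). Among 19 tested members 1 rose and 0 fell, 18 were not called, and adjusted over the list alone 9 rose and 1 fell. In the dasatinib 1x libraries the list summed to 1090 to 1120 CPM, against 776 to 931 CPM in the drug-free ones. Bbc3 was the member that rose. Oxidative phosphorylation rose as a list (median log2 change 0.06, adjusted p = 2.69e-05, and adjusted p = 0.775 with an estimated correlation). Of 50 tested members 0 rose, 0 fell and 50 were not called, and 0 rose and 0 fell when adjusted over the list alone. Summed over its members it held 11200 to 11800 CPM in the dasatinib 1x libraries and 10100 to 10900 CPM in the drug-free ones. Sterol biosynthesis fell as a list (median log2 change -0.14, adjusted p = 3.12e-05, and adjusted p = 0.775 with an estimated correlation). Among 24 tested members 0 rose and 1 fell, 23 were not called, and adjusted over the list alone 0 rose and 8 fell. Together its genes made up 2680 to 2740 CPM in the dasatinib 1x libraries and 2830 to 3200 CPM in the drug-free ones.

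Amino acid stress and integrated stress response genes rose as a list (median log2 change 0.1, adjusted p = 0.00453, and adjusted p = 0.775 with an estimated correlation). Of 25 tested members 1 rose, 0 fell and 24 were not called, and 9 rose and 2 fell when adjusted over the list alone. Its sum was 6470 to 6580 CPM in the dasatinib 1x libraries, against 5720 to 6240 CPM in the drug-free ones. The called member was Atf5, a stress-induced transcription factor (117 ± 2.14 against 62.2 ± 15.3 CPM, log2 change 0.91 ± 0.17, adjusted p = 0.037). Its adjusted p was 0.104 without DMSO 1x, 0.145 without dasatinib 1x A, 0.146 without dasatinib 1x B, 0.141 without dasatinib 1x C and 0.0571 without dasatinib 16x C (range over all alternatives 9.58e-06 to 0.147). Replication-dependent histones, whose mRNAs lack a poly(A) tail, rose as a list (median log2 change 1.27, adjusted p = 0.0306, and adjusted p = 0.924 with an estimated correlation). Among 36 tested members 0 rose and 0 fell, 36 were not called, and adjusted over the list alone 0 rose and 0 fell. The members summed to 36.6 to 148 CPM in the dasatinib 1x libraries and to 40.6 to 50.4 CPM in the drug-free ones. In this list dasatinib 1x B held 148 CPM, against 36.6 in A and 38.4 in C, and without B the list fell. Its adjusted p was 0.0296 without dasatinib 1x B, 0.0789 without DMSO 16x, 0.115 without parental A and 0.151 without parental B (range over all alternatives 4.64e-06 to 0.924). The test and the list's members differed in sign for lists that were not called: median, mean and test direction were those of ERK pathway output and feedback (0.02, -0.09, up), FOXO-induced genes (0.07, -0.17, up), cytosolic ribosomal proteins (-0.01, 0, up), glycolysis (0, -0.52, up), erythroid and megakaryocytic cells (-0.12, 0.25, down) and heat shock and dissociation-linked immediate early genes (-0.01, -0.08, up).

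By edgeR's quasi-likelihood test 241 of 12282 genes changed at 1x, 101 higher and 140 lower, of which 136 changed at least 2-fold. At an unadjusted p under 0.05 there were 2432. Of the calls, 15 higher and 7 lower were genes of chromosomes 5 and 18. The count depended on single libraries: it was 18 without dasatinib 1x A, 17 without B, 36 without C, 65 without DMSO 1x and 516 without DMSO 16x. Of the 32 called genes picked by the naming rule, 28 lost the call without at least 1 library.

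The second comparison set the dasatinib 16x lines (n = 3) against the same 4 drug-free libraries, to ask which genes differed at the highest dose step sequenced. Itgal rose to 179 ± 40.9 from 46.7 ± 3.01 CPM (log2 change 1.94 ± 0.13, adjusted p = 0.000211). Socs1 and Cish, feedback inhibitors induced by STAT5, rose to 23.4 ± 0.694 from 14.1 ± 0.893 CPM (log2 change 0.73 ± 0.07, adjusted p = 0.000287) and to 63.6 ± 8.96 from 35.6 ± 1.48 CPM (log2 change 0.84 ± 0.08, adjusted p = 0.000473). Cd74, the invariant chain of MHC class II, rose to 63.9 ± 7.93 from 25.6 ± 7.99 CPM (log2 change 1.32 ± 0.21, adjusted p = 0.00404). It lies on chromosome 18, whose genes were lower in the DMSO lines, yet the DMSO libraries (28.2 and 35.8 CPM) stood above the parental ones. Cd36, a scavenger receptor gene of chromosome 5, rose to 126 ± 31 from 64.2 ± 9.82 CPM (log2 change 0.97 ± 0.16, adjusted p = 0.00487), with DMSO 1x at 78.8 CPM and the other 3 drug-free libraries at 58.1 to 60.5 CPM. No overlap was again a condition for naming the highest and lowest genes, though not list members. Each called gene given with its level in this comparison had all 3 dasatinib libraries beyond all 4 drug-free ones. Those given with their level and no left-out value passed whichever library was left out, though some lost the call under another setting, as their ranges show. The ranges over all alternatives do not reflect the 2-fold threshold, under which any gene changed less than 2-fold loses its call. Abl1 was not called (178 ± 1.93 against 194 ± 11.3 CPM, log2 change -0.12 ± 0.04, adjusted p = 0.0981), but it was called as lower without DMSO 16x (adjusted p = 0.00347) and under other settings (range over all alternatives 0.00185 to 0.232).

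**Figure D2:**
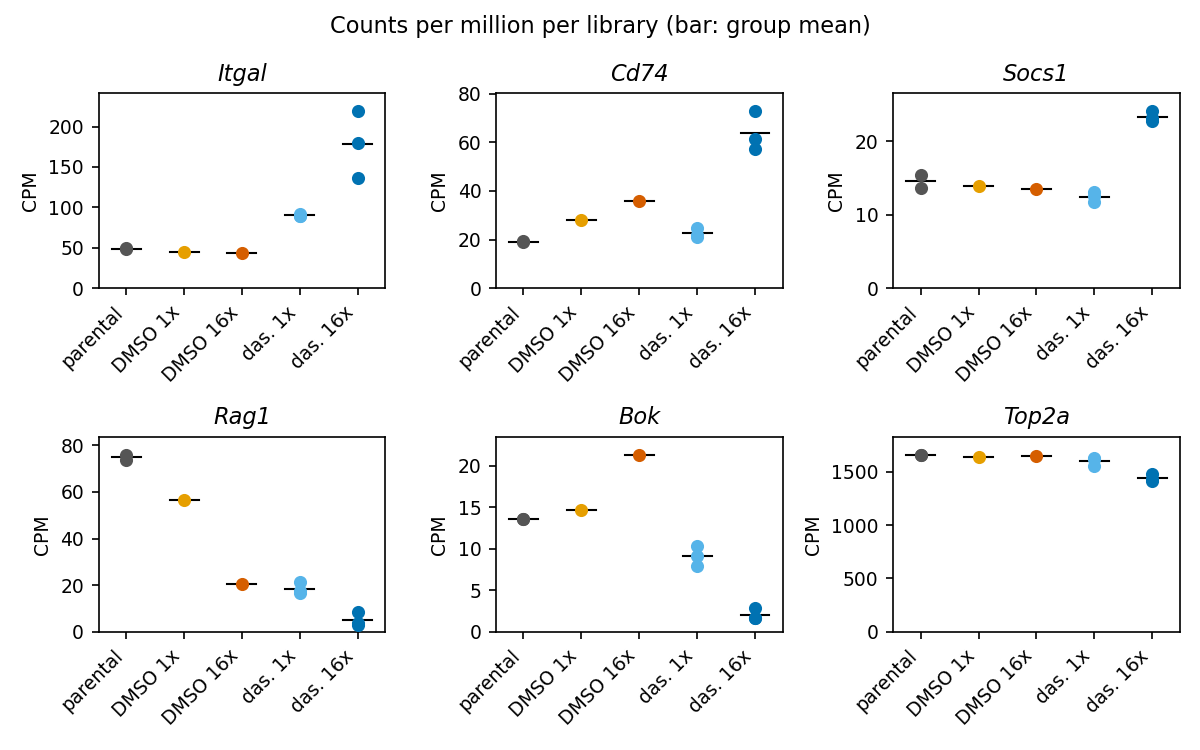
CPM of 6 genes in each library, by group, with a bar at the group mean. Itgal, Cd74 and Socs1 were highest in the 3 dasatinib 16x libraries, Bok was lowest in the 3 dasatinib 16x libraries and highest in DMSO 16x (21.3 CPM), and Rag1 in DMSO 16x (20.3 CPM) lay near the dasatinib 1x libraries.

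Rag1, a recombinase of the antigen receptor loci, fell to 5.12 ± 3.09 from 56.7 ± 25.8 CPM (log2 change -3.46 ± 0.53, adjusted p = 0.00358), and DMSO 16x (20.3 CPM) lay well below the parental libraries (73.8 and 76 CPM). Ikzf3, which encodes the transcription factor Aiolos, fell to 104 ± 2.57 from 163 ± 22.7 CPM (log2 change -0.64 ± 0.09, adjusted p = 0.00264). Bcl11a fell to 132 ± 5.46 from 162 ± 5.04 CPM (log2 change -0.29 ± 0.04, adjusted p = 0.00179). The pro-B and pre-B cell identity genes fell as a list (median log2 change -0.23, adjusted p = 0.00691, and adjusted p = 0.171 with an estimated correlation). Of 31 tested members 2 rose, 9 fell and 20 were not called, and 3 rose and 13 fell when adjusted over the list alone. In the dasatinib 16x libraries the list summed to 8010 to 8450 CPM, against 8750 to 9350 CPM in the drug-free ones. Among the members that rose was Cd38, and among those that fell Pax5 and Rag2. Cell adhesion and migration genes rose as a list (median log2 change 0.16, adjusted p = 0.0391, and adjusted p = 0.525 with an estimated correlation). Among 28 tested members 5 rose and 2 fell, 21 were not called, and adjusted over the list alone 6 rose and 3 fell. Summed over its members it held 4130 to 4300 CPM in the dasatinib 16x libraries and 3460 to 4050 CPM in the drug-free ones. The adhesion list's adjusted p was 0.0689 leaving out the genes of chromosomes 5 and 18, 0.0503 without dasatinib 16x B, 0.146 without parental A and 0.142 without parental B (range over all alternatives 0.000505 to 0.525).

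S phase and replication genes fell as a list (median log2 change -0.11, adjusted p = 9.04e-07, and adjusted p = 0.116 with an estimated correlation). Of 37 tested members 0 rose, 19 fell and 18 were not called, and 1 rose and 21 fell when adjusted over the list alone. Together its genes made up 7750 to 7830 CPM in the dasatinib 16x libraries and 8480 to 8690 CPM in the drug-free ones. Prim1, a DNA primase subunit, fell to 62.3 ± 1.25 from 76.8 ± 1.99 CPM (log2 change -0.3 ± 0.03, adjusted p = 0.000779) and Lig1, DNA ligase 1, to 225 ± 8.92 from 283 ± 10.1 CPM (log2 change -0.33 ± 0.04, adjusted p = 0.000813). G2 and mitosis genes fell as a list (median log2 change -0.12, adjusted p = 9.04e-07, and adjusted p = 0.171 with an estimated correlation). Among 38 tested members 0 rose and 17 fell, 21 were not called, and adjusted over the list alone 0 rose and 20 fell. Its sum was 9720 to 10200 CPM in the dasatinib 16x libraries, against 10900 to 11100 CPM in the drug-free ones. Ncapd2, a condensin subunit, fell to 491 ± 15.3 from 585 ± 5.17 CPM (log2 change -0.25 ± 0.03, adjusted p = 0.000862) and Top2a, topoisomerase 2 alpha, to 1440 ± 38.8 from 1650 ± 7.91 CPM (log2 change -0.2 ± 0.03, adjusted p = 0.00404).

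Members of the BCL2 family and p53-induced genes moved in both directions. Bok, a pro-death member, fell to 2.05 ± 0.7 from 15.8 ± 3.7 CPM (log2 change -2.94 ± 0.25, adjusted p = 0.000287), with DMSO 16x at 21.3 and the other drug-free libraries at 13.6 to 14.7 CPM. Pmaip1, the BH3-only gene NOXA of chromosome 18, fell to 8.68 ± 0.917 from 12.4 ± 1.02 CPM (log2 change -0.51 ± 0.1, adjusted p = 0.00839), with a range over all alternatives of 6.23e-05 to 0.0564. Bcl2l2, the survival gene BCL-W, rose to 46.5 ± 1.76 from 35.4 ± 1.26 CPM (log2 change 0.39 ± 0.04, adjusted p = 0.000624). Mcl1, another survival gene, fell to 210 ± 1.84 from 226 ± 2.44 CPM (log2 change -0.1 ± 0.03, adjusted p = 0.0254), and its adjusted p was 0.0503 without DMSO 1x, 0.0714 without dasatinib 16x A, 0.0724 without dasatinib 16x B, 0.0844 without dasatinib 16x C and 0.0555 without parental A (range over all alternatives 0.000211 to 0.151). Cdkn1a, the cell cycle inhibitor p21, rose to 95.2 ± 11.9 from 52.6 ± 11.5 CPM (log2 change 0.85 ± 0.15, adjusted p = 0.00629) and Rrm2b, a p53-induced ribonucleotide reductase subunit, to 73.4 ± 5.35 from 51.8 ± 3.23 CPM (log2 change 0.5 ± 0.07, adjusted p = 0.00196). The lists themselves were not called: p53-induced genes (5 rose and 4 fell of 19, list alone 5 and 4, median 0.13, adjusted p = 0.26), pro-survival BCL2 genes (1 rose and 1 fell of 5, list alone 1 and 3, median -0.1, adjusted p = 0.965) and pro-death BCL2 genes (2 rose and 2 fell of 9, list alone 5 and 2, median 0.19, adjusted p = 0.49).

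Metabolic lists were called at 16x in both directions. Oxidative phosphorylation rose as a list (median log2 change 0.1, adjusted p = 2.04e-06, and adjusted p = 0.631 with an estimated correlation). Of 50 tested members 11 rose, 0 fell and 39 were not called, and 13 rose and 0 fell when adjusted over the list alone. The members summed to 11400 to 11900 CPM in the dasatinib 16x libraries and to 10100 to 10900 CPM in the drug-free ones. Uqcrq, a subunit of complex III, rose to 126 ± 4.42 from 97.9 ± 3.21 CPM (log2 change 0.36 ± 0.06, adjusted p = 0.00625). Sterol biosynthesis fell as a list (median log2 change -0.2, adjusted p = 2.2e-05, and adjusted p = 0.532 with an estimated correlation). Among 24 tested members 0 rose and 6 fell, 18 were not called, and adjusted over the list alone 0 rose and 13 fell. In the dasatinib 16x libraries the list summed to 2550 to 2690 CPM, against 2830 to 3200 CPM in the drug-free ones. Amino acid stress and integrated stress response genes rose as a list (median log2 change 0.28, adjusted p = 3.49e-05, and adjusted p = 0.47 with an estimated correlation). Of 25 tested members 13 rose, 1 fell and 11 were not called, and 16 rose and 3 fell when adjusted over the list alone. Summed over its members it held 6720 to 7570 CPM in the dasatinib 16x libraries and 5720 to 6240 CPM in the drug-free ones. Phgdh, the first enzyme of serine synthesis, rose to 758 ± 18.5 from 643 ± 9.68 CPM (log2 change 0.24 ± 0.03, adjusted p = 0.00159) and Mthfd2, a mitochondrial folate enzyme, to 447 ± 26.2 from 371 ± 7.47 CPM (log2 change 0.27 ± 0.04, adjusted p = 0.00303). Atf4, Atf5 and Ddit3 were among the members that rose, and Stc2 was the one that fell. The glycolysis list was not called, glycolysis (3 rose and 2 fell of 22, list alone 3 and 2, median 0.14, adjusted p = 0.0867), while Pfkp, a phosphofructokinase, rose to 333 ± 9.24 from 240 ± 30.9 CPM (log2 change 0.47 ± 0.09, adjusted p = 0.00729). The list summed to 8850 and 8760 CPM in the parental libraries and 11600 and 11700 CPM in the DMSO lines. In dasatinib 16x it held 11200 to 11900 CPM. The drug-free class thus joined lower parental and higher DMSO levels, and no list test was made against the parental libraries alone.

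Interferon response genes rose as a list (median log2 change 0.23, adjusted p = 0.0304, and adjusted p = 0.47 with an estimated correlation). Among 32 tested members 4 rose and 1 fell, 27 were not called, and adjusted over the list alone 4 rose and 1 fell. Together its genes made up 892 to 903 CPM in the dasatinib 16x libraries and 723 to 795 CPM in the drug-free ones. Oas3, an interferon-induced gene of chromosome 5, rose to 0.92 ± 0.116 from 0.173 ± 0.0733 CPM (log2 change 2.42 ± 0.31, adjusted p = 0.00137), and Psmb8, an immunoproteasome subunit, to 255 ± 7.9 from 186 ± 17.9 CPM (log2 change 0.45 ± 0.07, adjusted p = 0.00303), while Ddx58 fell. The interferon list's adjusted p was 0.0621 leaving out the genes of chromosomes 5 and 18, 0.0671 without dasatinib 16x A and 0.0574 without dasatinib 16x B (range over all alternatives 0.0103 to 0.47). Icam1, an adhesion molecule induced by NF-kB, rose to 27.3 ± 1.7 from 22.5 ± 0.209 CPM (log2 change 0.28 ± 0.06, adjusted p = 0.0111) in a list that was not called, NF-kB induced genes (2 rose and 0 fell of 14, list alone 5 and 1, median 0.19, adjusted p = 0.106). Over all alternatives the adjusted p of Icam1 ranged over 0.000511 to 0.0544.

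Among kinases, Ryk, an atypical receptor tyrosine kinase, fell to 0.0325 ± 0.0375 from 30.1 ± 12.7 CPM (log2 change -9.77 ± 0.86, adjusted p = 0.000325), on 4 counts in the 3 libraries, with a range over all alternatives of 1.33e-24 to 0.054. Tyro3 rose to 11.5 ± 0.574 from 5.93 ± 0.719 CPM (log2 change 0.95 ± 0.11, adjusted p = 0.000862). Of the drug transporters, Abcb1b, a P-glycoprotein gene of chromosome 5, rose to 73.1 ± 3.79 from 53.6 ± 6.66 CPM (log2 change 0.45 ± 0.09, adjusted p = 0.00899) and Abcc1 fell to 0.0716 ± 0.124 from 2.75 ± 1.12 CPM (log2 change -5.22 ± 0.85, adjusted p = 0.00469). None of these lists was called: receptor tyrosine kinases (2 rose and 3 fell of 11, list alone 3 and 4, median -0.52, adjusted p = 0.406), ABL, SRC and TEC family kinases (1 rose and 1 fell of 18, list alone 0 and 1, median -0.03, adjusted p = 0.928), and ABC and SLC drug transporters (2 rose and 1 fell of 8, list alone 2 and 2, median 0.09, adjusted p = 0.928).

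Among genes that reached 5 CPM, large rises at 16x, besides Spna1 (5.37 ± 2.84 against 0.0521 ± 0.0503 CPM, log2 change 6.54 ± 0.6, adjusted p = 0.000354), were of Slc11a1, a metal ion transporter, to 6.09 ± 0.973 from 0.729 ± 0.172 CPM (log2 change 3.05 ± 0.2, adjusted p = 0.000211). Crisp1 rose to 40.7 ± 22.3 from 5.14 ± 2.57 CPM (log2 change 2.98 ± 0.44, adjusted p = 0.00308). Odz4 rose to 10.1 ± 2.91 from 1.3 ± 0.606 CPM (log2 change 2.96 ± 0.36, adjusted p = 0.00129). Mmp13, a collagenase, rose to 7.93 ± 2.08 from 1.15 ± 0.816 CPM (log2 change 2.79 ± 0.6, adjusted p = 0.0152), with a range over all alternatives of 1.91e-06 to 0.0616. Among the widest falls were again genes with 0 or few counts. Rnf130 was at least 500-fold lower (adjusted p = 0.00945) and Klhl22 at least 240-fold lower (adjusted p = 0.00738), with parental levels of 18.3 and 18.9 CPM for Rnf130 and 0.992 CPM in DMSO 16x. The bounds were 322 without dasatinib 16x A for Rnf130 and 155 without dasatinib 16x A for Klhl22. Eif5a2, a translation factor, had 1 count in the 3 libraries, a ratio of 3270 (95% counting interval 587 to 129000), with adjusted p = 0.00292, and the ratio was 2110 without dasatinib 16x A and at least 754 without dasatinib 16x B. Rps6kc1, at least 294-fold lower (adjusted p = 0.0125), and Fhl1, at least 274-fold lower (adjusted p = 0.013), stood highest in DMSO 16x, at 17.6 and 16.2 CPM, against parental levels of 1.5 and 1.36 CPM and of 1.43 and 1.32 CPM. The bound of Rps6kc1 was 141 without DMSO 16x and 190 without dasatinib 16x A, and that of Fhl1 134 without DMSO 16x and 177 without dasatinib 16x A. The range of adjusted p over all alternatives was 6.98e-12 to 0.167 for Rnf130, 1.03e-06 to 0.0671 for Klhl22 and 9.79e-13 to 0.287 for Eif5a2. It was 8.53e-08 to 0.0788 for Rps6kc1 and 4.59e-11 to 0.0745 for Fhl1. Kif13a, a kinesin gene that also stood highest in DMSO 16x, was at least 784-fold lower (adjusted p = 0.0266), with 46.2 CPM there, 4.12 and 4.23 CPM in the parental libraries and 0 counts in the 3 dasatinib 16x libraries. Its bound was 387 without DMSO 16x and 506 without dasatinib 16x A. The adjusted p of Kif13a was 0.0609 without DMSO 1x, 0.0581 without DMSO 16x, 0.0654 without dasatinib 16x A, 0.0547 without dasatinib 16x B and 0.0662 without dasatinib 16x C (range over all alternatives 4.01e-08 to 0.139).

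Of the other lists at 16x none was called. Signalling and stage lists were later B-cell stage and antigen presentation (4 rose and 1 fell of 19, list alone 6 and 4, median -0.01, adjusted p = 0.928) and STAT5-induced genes (5 rose and 2 fell of 17, list alone 6 and 5, median 0.12, adjusted p = 0.49). Others were ERK pathway output and feedback (3 rose and 1 fell of 20, list alone 3 and 1, median -0.01, adjusted p = 0.509) and FOXO-induced genes (5 rose and 4 fell of 22, list alone 6 and 6, median -0.06, adjusted p = 0.965). Growth lists were ribosome biogenesis and MYC-linked genes (2 rose and 2 fell of 32, list alone 2 and 1, median 0.01, adjusted p = 0.928) and cytosolic ribosomal proteins (3 rose and 0 fell of 57, list alone 2 and 0, median 0.02, adjusted p = 0.428). The 3 ribosomal protein genes that rose were Rps14, Rplp0 and Rpl5, and Rps14 (950 ± 13.7 against 803 ± 56.2 CPM) and Rplp0 (3950 ± 16.2 against 3440 ± 202 CPM) are genes of chromosomes 18 and 5 that were lowest in DMSO 16x. The former rose with log2 change 0.24 ± 0.06, adjusted p = 0.0182, the latter with log2 change 0.2 ± 0.05, adjusted p = 0.0191. For Rps14 the adjusted p was 0.0548 without dasatinib 16x A and 0.0647 without dasatinib 16x C (range over all alternatives 4.48e-05 to 0.0839), and for Rplp0 0.058 without dasatinib 16x A and 0.0629 without dasatinib 16x C (range over all alternatives 4.48e-05 to 0.106).

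Lists of other cells were not called either, namely myeloid cells (1 rose and 0 fell of 7, list alone 1 and 0, median 0.03, adjusted p = 0.965), T and NK cells (2 rose and 1 fell of 7, list alone 2 and 1, median 0.38, adjusted p = 0.49) and erythroid and megakaryocytic cells (1 rose and 1 fell of 7, list alone 1 and 1, median 0.15, adjusted p = 0.965). Nor were lists of stress and RNA quality, namely heat shock and dissociation-linked immediate early genes (4 rose and 2 fell of 18, list alone 4 and 2, median 0, adjusted p = 0.987), mitochondrial and nuclear-retained RNAs (0 rose and 0 fell of 6, list alone 0 and 0, median -0.1, adjusted p = 0.965) and replication-dependent histones (0 rose and 0 fell of 36, list alone 0 and 0, median -0.13, adjusted p = 0.928). Of the 24 genes of the mitochondrial and nuclear-retained list only 8 were among the genes counted, and the 6 tested summed to 444 to 762 CPM. That list therefore does not show whether mitochondrial RNA changed. The stromal and endothelial list had 2 tested members and was not tested, and its summed level was 48.6 to 61.2 CPM. Cd2, an adhesion receptor of T cells, rose to 234 ± 8.3 from 128 ± 26.2 CPM (log2 change 0.87 ± 0.13, adjusted p = 0.00331). Tcf7, a T-cell transcription factor, rose to 14.8 ± 3.47 from 8.35 ± 0.61 CPM (log2 change 0.82 ± 0.14, adjusted p = 0.00541). Gp9, a platelet membrane gene, rose to 0.667 ± 0.396 from 0.0529 ± 0.059 CPM (log2 change 3.69 ± 0.73, adjusted p = 0.0105). Tfrc fell to 706 ± 27.7 from 989 ± 35.7 CPM (log2 change -0.49 ± 0.04, adjusted p = 0.000247). Zfp36, whose protein destabilises mRNAs, fell to 22.7 ± 1.61 from 32.7 ± 1.28 CPM (log2 change -0.53 ± 0.06, adjusted p = 0.000759). Median, mean and test direction differed in sign for later B-cell stage and antigen presentation (-0.01, -0.4, up), ERK pathway output and feedback (-0.01, 0.07, up), p53-induced genes (0.13, -0.37, up), BCL2 family, pro-death (0.19, -0.22, up), ABC and SLC drug transporters (0.09, -0.54, up), glycolysis (0.14, -0.31, up), heat shock and dissociation-linked immediate early genes (0, -0.09, up) and mitochondrially encoded RNAs and nuclear-retained RNAs (-0.1, -0.28, up).

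In the test at 16x 1980 genes changed, 957 higher and 1023 lower, of which 492 changed at least 2-fold. Of these, 162 higher and 26 lower were genes of chromosomes 5 and 18. The count was 1302 without DMSO 1x, 1058 without dasatinib 16x A and 1005 without C. Of the 66 called genes that the naming rule picks, 51 passed whichever library was left out.

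The third comparison set dasatinib 16x against 1x (n = 3 each), to ask what differed between the later and the earlier step of escalation. Socs1 rose to 23.4 ± 0.694 from 12.4 ± 0.664 CPM (log2 change 0.91 ± 0.07, adjusted p = 0.00294). Bok fell to 2.05 ± 0.7 from 9.09 ± 1.18 CPM (log2 change -2.14 ± 0.26, adjusted p = 0.00624). Tyro3 rose to 11.5 ± 0.574 from 5.81 ± 0.493 CPM (log2 change 0.98 ± 0.12, adjusted p = 0.00624). Sox6, a transcription factor, rose to 36.8 ± 6.17 from 7.94 ± 0.479 CPM (log2 change 2.21 ± 0.24, adjusted p = 0.00566). Ryk fell to 0.0325 ± 0.0375 from 6.21 ± 3.29 CPM (log2 change -7.49 ± 0.91, adjusted p = 0.0065). Aes, a co-repressor gene, fell to 0.0325 ± 0.0375 from 15.3 ± 4.85 CPM (log2 change -8.8 ± 0.94, adjusted p = 0.00562). Cand2 fell to 2.25 ± 0.15 from 8.07 ± 0.0566 CPM (log2 change -1.84 ± 0.25, adjusted p = 0.00814). These 7 genes passed whichever library was left out, but over all alternatives the adjusted p ranged over 3.92e-13 to 0.267 for Ryk and 8.86e-17 to 0.206 for Aes, so both calls were lost under another setting. Here too the highest and lowest genes were named only if the groups did not overlap. For each called gene given with its level in this comparison the 3 libraries of 16x lay beyond the 3 of 1x. The same was true of Abl1 (178 ± 1.93 against 198 ± 2.39 CPM, log2 change -0.15 ± 0.05, adjusted p = 0.139), which was not called, but was without DMSO 16x (adjusted p = 0.0104) and under other settings (range over all alternatives 0.00312 to 0.328).

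Cd74, of chromosome 18, rose to 63.9 ± 7.93 from 22.6 ± 1.94 CPM (log2 change 1.5 ± 0.23, adjusted p = 0.0151). Lta, the cytokine lymphotoxin alpha, rose to 389 ± 49.7 from 135 ± 4.72 CPM (log2 change 1.53 ± 0.25, adjusted p = 0.0214). Oas3, of chromosome 5, rose to 0.92 ± 0.116 from 0.135 ± 0.0142 CPM (log2 change 2.74 ± 0.35, adjusted p = 0.00662). Itgal rose to 179 ± 40.9 from 90.3 ± 1.6 CPM (log2 change 0.99 ± 0.14, adjusted p = 0.0118) and Cish to 63.6 ± 8.96 from 40 ± 2.03 CPM (log2 change 0.67 ± 0.09, adjusted p = 0.0094). Pmaip1, of chromosome 18, fell to 8.68 ± 0.917 from 13.9 ± 0.935 CPM (log2 change -0.68 ± 0.1, adjusted p = 0.0138), and Pcna, the DNA polymerase clamp, to 614 ± 5.24 from 699 ± 8.31 CPM (log2 change -0.19 ± 0.03, adjusted p = 0.0215). Without single libraries the adjusted p of Cd74 was 0.0887 without dasatinib 1x A, 0.0626 without dasatinib 1x B and 0.092 without dasatinib 1x C (range over all alternatives 4.18e-09 to 0.092). For Oas3 it was 0.0533 without dasatinib 1x C (range over all alternatives 3.58e-05 to 0.0533). That of Lta was 0.113 without dasatinib 1x A, 0.0901 without dasatinib 1x B, 0.107 without dasatinib 1x C, 0.0619 without dasatinib 16x A and 0.063 without dasatinib 16x C (range over all alternatives 2.27e-05 to 0.113). That of Itgal was 0.0771 without dasatinib 1x A, 0.0581 without dasatinib 1x B and 0.07 without dasatinib 1x C (range over all alternatives 1e-09 to 0.0771). For Cish it was 0.053 without dasatinib 1x B and 0.0685 without dasatinib 1x C (range over all alternatives 2.26e-08 to 0.0685). For Pmaip1 it was 0.0887 without dasatinib 1x A, 0.0578 without dasatinib 1x B, 0.0685 without dasatinib 1x C and 0.0596 without dasatinib 16x C (range over all alternatives 9.77e-07 to 0.0887). For Pcna it was 0.113 without dasatinib 1x A, 0.105 without dasatinib 1x B, 0.107 without dasatinib 1x C, 0.0563 without dasatinib 16x A, 0.0603 without dasatinib 16x B and 0.093 without dasatinib 16x C (range over all alternatives 6.2e-08 to 0.113).

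Rnf130 had 0 counts at 16x and was at least 328-fold lower than at 1x (7.67 ± 2.92 CPM, adjusted p = 0.0449). The bound was 212 without dasatinib 16x A. Its adjusted p was 0.0786 without DMSO 1x, 0.139 without dasatinib 1x A, 0.105 without dasatinib 1x B, 0.141 without dasatinib 1x C, 0.103 without dasatinib 16x A, 0.0884 without dasatinib 16x B, 0.112 without dasatinib 16x C, 0.0664 without parental A and 0.067 without parental B (range over all alternatives 1.67e-09 to 0.337). Eif5a2 was lower by a ratio of 1380 (95% counting interval 247 to 54400), with adjusted p = 0.0225. The ratio was 888 without dasatinib 16x A and at least 317 without dasatinib 16x B. Its adjusted p was 0.0887 without dasatinib 1x A, 0.0535 without dasatinib 1x B, 0.0837 without dasatinib 1x C, 0.0853 without dasatinib 16x A, 0.0952 without dasatinib 16x B and 0.0985 without dasatinib 16x C (range over all alternatives 4.41e-09 to 0.526). In DMSO 16x Rnf130 stood at 0.992 CPM and Eif5a2 at 2.25 CPM, against parental levels of 18.3 and 18.9 CPM and of 39.4 and 38.2 CPM. Cd38, an ectoenzyme gene of chromosome 5, rose to 22.4 ± 11.3 from 6.02 ± 0.415 CPM (log2 change 1.9 ± 0.35, adjusted p = 0.0286), and its adjusted p was 0.0545 without DMSO 1x, 0.126 without dasatinib 1x A, 0.122 without dasatinib 1x B and 0.141 without dasatinib 1x C (range over all alternatives 1.53e-06 to 0.141).

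Of 28 lists 12 were called between the steps, and the cell cycle lists were the 2 that passed with an estimated correlation. S phase and replication genes fell as a list (median log2 change -0.14, adjusted p = 1.77e-12, and adjusted p = 0.0211 with an estimated correlation). Of 37 tested members 0 rose, 4 fell and 33 were not called, and 0 rose and 20 fell when adjusted over the list alone. Its sum was 7750 to 7830 CPM in the dasatinib 16x libraries, against 8550 to 8620 CPM in the dasatinib 1x ones. G2 and mitosis genes fell as a list (median log2 change -0.11, adjusted p = 1.77e-12, and adjusted p = 0.0477 with an estimated correlation). Among 38 tested members 0 rose and 6 fell, 32 were not called, and adjusted over the list alone 0 rose and 17 fell. The members summed to 9720 to 10200 CPM in the dasatinib 16x libraries and to 10700 to 11000 CPM in the dasatinib 1x ones. Interferon response genes rose as a list (median log2 change 0.3, adjusted p = 4.88e-06, and adjusted p = 0.059 with an estimated correlation). Of 32 tested members 1 rose, 0 fell and 31 were not called, and 5 rose and 0 fell when adjusted over the list alone. In the dasatinib 16x libraries the list summed to 892 to 903 CPM, against 760 to 805 CPM in the dasatinib 1x ones. Later B-cell stage and antigen presentation genes rose as a list (median log2 change 0.5, adjusted p = 0.00419, and adjusted p = 0.426 with an estimated correlation). Among 19 tested members 1 rose and 0 fell, 18 were not called, and adjusted over the list alone 3 rose and 0 fell. Summed over its members it held 1120 to 1170 CPM in the dasatinib 16x libraries and 1060 to 1090 CPM in the dasatinib 1x ones. Cell adhesion and migration genes rose as a list (median log2 change 0.11, adjusted p = 0.00419, and adjusted p = 0.192 with an estimated correlation). Of 28 tested members 3 rose, 0 fell and 25 were not called, and 9 rose and 1 fell when adjusted over the list alone. Together its genes made up 4130 to 4300 CPM in the dasatinib 16x libraries and 3720 to 3780 CPM in the dasatinib 1x ones.

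NF-kB induced genes rose as a list (median log2 change 0.25, adjusted p = 0.00644, and adjusted p = 0.192 with an estimated correlation). Among 14 tested members 2 rose and 0 fell, 12 were not called, and adjusted over the list alone 3 rose and 0 fell. Its sum was 725 to 835 CPM in the dasatinib 16x libraries, against 473 to 482 CPM in the dasatinib 1x ones. Most of this difference came from Lta alone, with means of 389 and 135 CPM. Between the DMSO lines, 1 library each, the same list stood at 564 CPM at 1x and 685 CPM at 16x. There STAT5-induced genes rose from 3720 to 3960 CPM, cell adhesion from 3840 to 4050 CPM, and later B-cell stage from 1070 to 1180 CPM. Interferon response fell from 766 to 723 CPM, and S phase (8690 and 8640 CPM) and G2 and mitosis genes (10900 and 11000 CPM) differed little. Where the DMSO lines rose too, dose step and time in culture cannot be told apart. STAT5-induced genes rose as a list (median log2 change 0.18, adjusted p = 0.00683, and adjusted p = 0.192 with an estimated correlation). Of 17 tested members 2 rose, 0 fell and 15 were not called, and 3 rose and 0 fell when adjusted over the list alone. The members summed to 3980 to 4070 CPM in the dasatinib 16x libraries and to 3660 to 3740 CPM in the dasatinib 1x ones. Pro-B and pre-B cell identity genes fell as a list (median log2 change -0.09, adjusted p = 0.00726, and adjusted p = 0.161 with an estimated correlation). Among 31 tested members 1 rose and 0 fell, 30 were not called, and adjusted over the list alone 1 rose and 3 fell. In the dasatinib 16x libraries the list summed to 8010 to 8450 CPM, against 8480 to 8700 CPM in the dasatinib 1x ones. Its called member Cd38 rose, against the direction of the list. Glycolysis rose as a list (median log2 change 0.17, adjusted p = 0.0192, and adjusted p = 0.787 with an estimated correlation). Of 22 tested members 0 rose, 0 fell and 22 were not called, and 0 rose and 0 fell when adjusted over the list alone. Summed over its members it held 11200 to 11900 CPM in the dasatinib 16x libraries and 10300 to 10700 CPM in the dasatinib 1x ones. DMSO 1x and DMSO 16x held 11600 and 11700 CPM, and the parental libraries 8850 and 8760 CPM. Amino acid stress and integrated stress response genes rose as a list (median log2 change 0.17, adjusted p = 0.00585, and adjusted p = 0.507 with an estimated correlation). Among 25 tested members 0 rose and 0 fell, 25 were not called, and adjusted over the list alone 1 rose and 0 fell. Together its genes made up 6720 to 7570 CPM in the dasatinib 16x libraries and 6470 to 6580 CPM in the dasatinib 1x ones. DMSO 1x stood at 5920 CPM and DMSO 16x at 6240 CPM. The stress list's adjusted p was 0.367 without dasatinib 16x A (range over all alternatives 0.000878 to 0.507).

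The p53-induced genes fell as a list (median log2 change -0.05, adjusted p = 0.0197, and adjusted p = 0.243 with an estimated correlation). Of 19 tested members 0 rose, 3 fell and 16 were not called, and 0 rose and 4 fell when adjusted over the list alone. Its sum was 987 to 1160 CPM in the dasatinib 16x libraries, against 1090 to 1120 CPM in the dasatinib 1x ones. DMSO 1x held 871 CPM and DMSO 16x 776 CPM, 1 library each. Since the list was lower in DMSO 16x too, dose step and time in culture cannot be told apart here. The members that fell were Pmaip1, Ckap2 and Phlda3, and the adjusted p was 0.0853 leaving out the genes of chromosomes 5 and 18 and 0.0658 without dasatinib 16x A (range over all alternatives 0.00983 to 0.243). Replication-dependent histones fell as a list (median log2 change -1.39, adjusted p = 0.00419, and adjusted p = 0.789 with an estimated correlation). Among 36 tested members 0 rose and 0 fell, 36 were not called, and adjusted over the list alone 0 rose and 0 fell. The members summed to 38 to 43.2 CPM in the dasatinib 16x libraries and to 36.6 to 148 CPM in the dasatinib 1x ones. The level of dasatinib 1x B, 148 CPM, set the direction: without it the list stood higher at 16x, and the adjusted p was 0.0952 without dasatinib 1x B (range over all alternatives 5.69e-08 to 0.789). Among lists that were not called, median, mean and test direction differed in sign for BCL2 family, pro-death (0.04, -0.27, down), ABC and SLC drug transporters (0.04, -0.12, up), T and NK cells (0.05, -0.04, up), erythroid and megakaryocytic cells (-0.01, 0.32, down) and heat shock and dissociation-linked immediate early genes (0.02, -0.01, down).

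Between the steps 262 genes changed, 148 higher and 114 lower at 16x, of which 82 changed at least 2-fold. At an unadjusted p under 0.05 there were 1942. The count was 45 without dasatinib 1x A, 55 without B and 41 without C, 155 without dasatinib 16x A and 88 without C, 135 without DMSO 1x and 978 without DMSO 16x. Of 35 called genes picked by the naming rule 28 lost the call without at least 1 library.

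The first and second comparisons share their controls. Of the genes called in both, 216 changed in the same direction, 95 higher and 121 lower, and 0 in opposite directions. All 10 libraries, controls included, were also simulated without change from the drug-free mean, and each of 20 draws gave 0 such genes. These draws called a mean of 0.2 and 0.05 genes in the 2 comparisons, so they had almost none to share. Their 0 does not show how much of the overlap comes from the shared controls. Independent lists of the observed sizes would share 7.87 higher and 11.66 lower genes. Over 8963 genes the log2 changes had r = 0.73, against 0.425 simulated (0.391 to 0.476), and genes are not independent replicates. Their covariance was 0.155 against 0.0096 simulated, a difference of 0.145. The controls were also split, in the fit of 5 groups, so that the fit changed together with the controls. With parental controls for 1x and DMSO controls for 16x, 514 genes changed in the same direction and 31 in the opposite one (69.55 higher and 60.67 lower for independent lists, r = 0.728), with a covariance of 0.129. With the controls exchanged, 940 and 665 did so (294.2 and 255.8, r = 0.287), with a covariance of 0.0752. The overlap was 17 to 443 genes when 1 library was left out.

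The dasatinib lines were also set against the DMSO library of the same step, which asks how they differed from a line carried to the same step with the solvent. Each control is 1 library, whose spread is taken to be that of the other groups. Against DMSO 1x, Mmp13 rose to 11.1 ± 1.71 from 0.958 CPM (log2 change 3.54 ± 0.36, adjusted p = 0.000232) and Micall2, of chromosome 5, to 15.4 ± 4.19 from 2.6 CPM (log2 change 2.56 ± 0.44, adjusted p = 0.0112). Spna1 had 2 counts in DMSO 1x, a ratio of 155 (95% counting interval 42.8 to 1280), with adjusted p = 0.0116. Kif13a, Casd1 and Slc25a13 had 0 counts in the 3 dasatinib 1x libraries and were at least 696-fold, 547-fold and 486-fold lower, with adjusted p of 5.08e-07, 7.71e-07 and 1.04e-06. Without dasatinib 1x B, and without C, these bounds were 447, 351 and 312. All of these passed whichever of the other 9 libraries was left out, while the DMSO library itself cannot be left out. The 3 dasatinib libraries lay beyond the DMSO library, as the naming rule required. In all, 843 genes were higher and 818 lower at 1x. Of these, 469 higher and 27 lower lay on chromosomes 5 and 18, and without the genes of those chromosomes 384 were higher and 604 lower.

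Against DMSO 16x, Psd3 rose to 11.7 ± 6.76 from 0.161 CPM (log2 change 6.16 ± 1.06, adjusted p = 0.00638). Spna1 was at least 66.8-fold higher (adjusted p = 0.0049), and Mmp13, with 3 counts in DMSO 16x, had a ratio of 98.5 (95% counting interval 33.6 to 479) and adjusted p = 6.6e-06. Kif13a was at least 1980-fold, Casd1 at least 1480-fold and Hoxb8, a homeobox gene, at least 1230-fold lower, with adjusted p of 2.28e-08, 5.13e-08 and 1.35e-07. Without dasatinib 16x A these bounds were 1270, 953 and 796. These genes passed whichever of the other 9 libraries was left out, while the DMSO library itself cannot be left out. By the naming rule, all 3 dasatinib libraries lay beyond the DMSO library. In all, 2320 genes were higher and 2062 lower, with 763 of the higher and 32 of the lower ones on chromosomes 5 and 18. Without the genes of those chromosomes 1642 were higher and 1771 lower, so that more were lower than higher.

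The last comparisons set the DMSO lines against the parental line (n = 2), to ask what changed in culture without drug. Hoxb8 rose from 0.773 ± 0.112 CPM to 10.8 CPM in DMSO 1x (log2 change 3.81 ± 0.23, adjusted p = 0.000222) and 28.9 CPM in DMSO 16x (log2 change 5.23 ± 0.23, adjusted p = 2.11e-06), while the dasatinib 16x libraries held 0 counts. Slc2a3, the glucose transporter GLUT3, rose to 7.77 from 0.694 ± 0.0664 CPM (log2 change 3.47 ± 0.31, adjusted p = 0.000159) in DMSO 1x. Cdh24, a cadherin gene, fell to 6.62 from 13.3 ± 0.152 CPM (log2 change -1 ± 0.17, adjusted p = 0.0058), and its adjusted p was 0.0563 without parental B (range over all alternatives 9.17e-05 to 0.0563). In DMSO 16x, Tspan8, a tetraspanin gene, rose to 6.11 from 0.0921 ± 0.0626 CPM (log2 change 6.11 ± 0.68, adjusted p = 4.65e-05). Fut4, a fucosyltransferase gene, fell to 0.348 from 14.7 ± 1.56 CPM (log2 change -5.38 ± 0.18, adjusted p = 3.11e-09). Gng12, a G protein subunit gene, was at least 152-fold lower (adjusted p = 7.96e-07), and Phlda3, a p53-induced gene with 3 counts, had a ratio of 73.4 (95% counting interval 24.9 to 357) and adjusted p = 0.000906. Each DMSO library lay beyond both parental libraries for these genes, as the naming rule required.

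Genes of chromosomes 5 and 18 stood lower in both DMSO lines. In DMSO 16x the median log2 ratio to the parental mean was -0.45 over 597 genes of chromosome 5 and -0.49 over 224 genes of chromosome 18, and in DMSO 1x -0.16 and -0.15. The other chromosomes had medians of 0 to 0.09 in the DMSO lines. In the 6 dasatinib libraries chromosome 5 had medians of 0.07 to 0.1 and chromosome 18 of -0.02 to 0.04. Against the parental line, 406 genes were higher and 352 lower in DMSO 1x, with 13 higher and 195 lower on these chromosomes, and without them 277 were higher and 141 lower. In DMSO 16x 1801 were higher and 1995 lower, with 36 and 728 on these chromosomes, and without them 1554 were higher and 1284 lower, so that more were higher than lower. The DMSO 1x count of 758 was 165 without parental A, 110 without parental B, 1410 without dasatinib 16x A and 1251 without dasatinib 16x B.

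**Figure D3:**
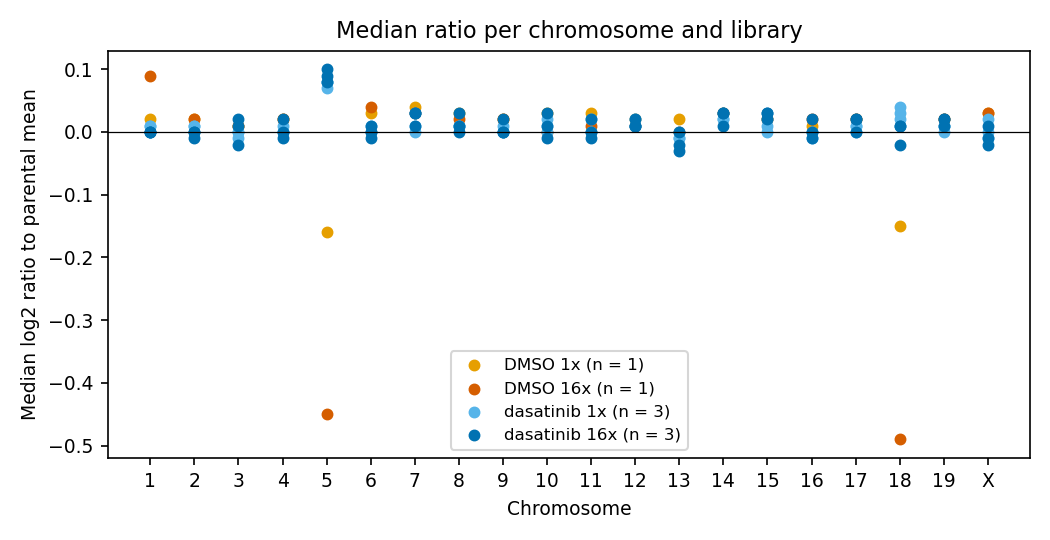
Median log2 ratio to the parental mean of the genes of each chromosome, for each DMSO and dasatinib library (points). Chromosomes 5 and 18 stand at -0.45 and -0.49 in DMSO 16x and at -0.16 and -0.15 in DMSO 1x, and chromosome 5 at 0.07 to 0.1 in the dasatinib libraries.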

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

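The tests of the 3 patterns and the counts of other splits were chosen only after the results were seen. By a test for a single outlying value among the 4 drug-free libraries, Bok stood out in DMSO 16x (0.857), Cfp in DMSO 16x (0.834) and Cd36 in DMSO 1x (0.883). These are 3 of 81 named genes, and chance gives about 1 in 20. The dasatinib against DMSO difference changed between 1x and 16x for 828 genes, and for Mmp13 by 3.03 on the log2 scale, which rests on single DMSO libraries.

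Other splits of the libraries into groups of the same sizes were counted. For genes, only the real split of 35 reached 241 calls at 1x (highest other 0), and only the real split of 35 reached 1980 at 16x (highest other 493), 1 split of 35 in both, the fewest that 35 splits can give. So chance can be excluded for these counts of calls only if the libraries vary independently, and nothing shows that they came from separate cultures. For lists, 21 of 35 splits reached the 5 calls at 1x (highest other 10) and 8 of 35 the 8 calls at 16x (highest other 12), so chance cannot be excluded for the counts of lists. For 16x against 1x the 10 splits are too few for a share under 0.05: 1 split reached the 262 genes (highest other 0) and 2 reached the 12 lists (highest other 12).

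A set of 24 genes had at most 6 counts over the 6 dasatinib libraries and at least 2 CPM in DMSO 16x, with a parental median of 8.11% of DMSO 16x. All 24 lay below the counts expected at the parental level. The limit on dasatinib counts and the filter on low counts fixed this in advance, so that comparison alone cannot decide on depth. The total counts argue against depth for the set. They were 31695307 to 45813092 in the 6 dasatinib libraries and 37160252 in DMSO 16x, where the set stood highest. Of the dasatinib libraries, only dasatinib 1x A had a lower total than DMSO 16x. Myeloid, T or stromal cells are argued against by low levels in DMSO 16x of the markers looked at. Lyz2 stood at 3.16 CPM, Mpo at 0.0268 CPM, and S100a8, S100a9, Cd3e, Col1a1 and Col1a2 had 0 counts. Cd2, of the T and NK list, stood at 162 CPM there but higher, at 234 ± 8.3 CPM, in dasatinib 16x, where the set has few or no reads. For erythroid cells a first test on a globin level (Hbb-b1, 34.4 CPM in DMSO 16x) could not decide. A second, chosen after its values were seen, found Hbb-b1 in dasatinib 16x at 65% of DMSO 16x and the set at a median of 0%. The set's value was fixed by the limit on its dasatinib counts, so this test rests on Hbb-b1 alone. Whether 1 part of the cells lies behind both this set and the fall of chromosomes 5 and 18 cannot be told apart from several parts or changing levels: the shares differed by -0.06, with an interval over genes of -0.09 to -0.01 that leaves out 0 and goes against 1 part, but each DMSO step is 1 library and the set was chosen by its DMSO 16x level.

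Genes of chromosomes 5 and 18 were lower in the DMSO lines. GC content or length as the whole cause is argued against by a gap of -0.49 before and -0.48 after regression on both (-0.49 to -0.46), and a fault of the DMSO 16x library alone by the same 2 chromosomes being the 2 lowest of 20 in DMSO 1x. Loss of copies along the whole chromosomes in part of the cells may lie behind it, as a hypothesis: with each chromosome parted into 4 along its length, all 8 parts had lower medians in DMSO 16x, the smallest fall being -0.39. DNA was not analysed here.

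Histone mRNAs were 3.94 times as high in dasatinib 1x B as in A and C. Less complete poly(A) selection may be the source, since Rmrp and Rpph1, RNAs without a poly(A) tail, stood 16.4 times as high. More cells in S phase is argued against by a ratio of 1.01 for the S phase list, and depth by a ratio of 1.12 for the effective library size.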

How the results depend on the processing

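Alternatives moved many counts, and their causes were not tested unless a value is given. For dasatinib 1x against drug-free (241 genes) DESeq2 gave 853, limma-voom 150, the block by replicate letter 54, the 2-fold threshold 136, parental libraries alone 708 and DMSO libraries alone 4149. For 16x (1980) the 2 classes alone gave 995, 2-fold 492, parental alone 3252 and DMSO alone 4518. For 16x against 1x (262) DESeq2 gave 805, the block 408, the 2 classes alone 1222 and 2-fold 82. For the overlap (216), chosen after seeing the data as were the next 2 alternatives, DESeq2 gave 666, the block 51, 2-fold 118, parental alone 603 and DMSO alone 3078. The parental and DMSO references were used with the fit of 5 groups, so fit and reference changed together. That fit with the whole reference gave 3449, 4542, 1669 and, for the overlap, 2473. Without the genes of chromosomes 5 and 18, dasatinib 1x against DMSO 1x fell from 1661 to 988 genes and DMSO 1x against parental from 758 to 418. RLE scaling and no filter moved no count of genes by over 1.5 times. With 1 library left out the counts ranged over 17 to 516 for 1x, 1005 to 2765 for 16x, 41 to 978 for 16x against 1x, 110 to 1410 for DMSO 1x against parental and 17 to 443 for the overlap. Of lists (5, 8 and 12 called) an estimated correlation gave 0, 0 and 2, and for 1x fry gave 3 and the block 9. At 1x the calls lost with fry included sterol biosynthesis (adjusted p = 0.114), oxidative phosphorylation (0.214) and amino acid stress (0.214), and the block lost sterol biosynthesis (0.0676). For 16x against 1x those lost with fry included later B-cell stage (0.0681), glycolysis (0.42) and amino acid stress (0.146). With 1 library left out lists numbered 5 to 6, 6 to 10 and 11 to 15. The log2 change of Abl1 at 1x, 0.03, was -0.01 with the block, with parental libraries alone and without DMSO 16x, and ranged from -0.01 to 0.06 with 1 library left out. With 1 library left out the adjusted p of the histone list ranged from 4.64e-06 to 0.151 at 1x and from 5.69e-08 to 0.0952 for 16x against 1x. It was 0.924 and 0.789 with an estimated correlation and 0.622 and 0.542 with fry, and without dasatinib 1x B its direction reversed in both, at 0.0296 and 0.0952. Of 160 named results 40 were the same under every alternative. Deviations of same-letter libraries at 1x and 16x had r of 0.065, 0.027 and 0.052. Those of different letters had r of -0.052 to 0.009. Deviations were taken from each group's own mean, so higher same-letter values push the different-letter ones down. The values are small and cannot decide on a link between letters. The main fit without pairing had been fixed before the data were examined.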

Other observations

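Neighbouring homeobox genes of the HoxB cluster, chosen after their values were seen, stood highest in DMSO 16x and were near 0 in the dasatinib lines. From the parental line over DMSO 1x to DMSO 16x, Hoxb8 stood at 0.773, 10.8 and 28.9 CPM, Hoxb6 at 0.437, 4.05 and 13.3 CPM, and Hoxb7 at 0.287, 3.86 and 10.6 CPM. Hoxb3 stood at 0.242, 1.67 and 5.52 CPM, Hoxb5 at 0.224, 1.53 and 5.23 CPM, and Hoxb4 at 1.05, 2.79 and 4.77 CPM. Over the 6 dasatinib libraries Hoxb8, Hoxb3 and Hoxb5 had 0 counts, Hoxb4 and Hoxb7 had 1 each and Hoxb6 had 2. No test was made of the cluster as a group.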
